A study of Homo sapiens with 24 samples.

How the data were processed

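RNA sequencing was carried out on CH-157MN and IOMM-Lee, 2 human lines from meningioma. Cells were exposed for 24 h to DMSO as the vehicle, to 78 nM digitoxin, to 2 nM torin 2, or to both agents at these concentrations, with 3 libraries in each of the 8 groups. The labels give a DMSO concentration for the control groups only, so whether the drug groups held the same amount is not known. Per the labels' protocols, RNA was purified on columns, mRNA was selected, libraries were made with a stranded Illumina kit, and single-end reads of 50 bp were produced, at a stated depth several times the total counts found here. Per the submitters' processing notes, STAR, RSEM and the GRCh38 build were used. Tool versions and the strand setting of the counting were not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

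The authors deposited 1 table of 59526 entries per library, which holds an expected count, a TPM value and an effective length for each gene, per the file headers. Expected counts are estimates of reads per gene with no normalization, so they were rounded to whole numbers before the count test. The deposited TPM values are expected counts divided by effective length and scaled to the same sum in each library, and they entered 1 alternative only. Of the entries, 58780 carried human gene identifiers, and all 58780 were found in GENCODE release 29, which gave symbols, classes, exons and coordinates on GRCh38. The other entries, 649 named by a number and 97 named as spike-ins, held 0.000273 to 0.00188% of the counts of a library and stayed out of library sizes and tests.

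Counts may lie on the opposite strand in the deposited tables, which is possible here because the kit marks strand, but this could not be settled from them. Antisense features held more counts than abundant coding genes on the other strand: mean expected counts over 24 libraries were 25150 for VIM-AS1 and 1214 for VIM, and 30450 for AC011603.2 and 184 for TUBA1B. Of the counts pooled over 487 pairs of an antisense feature and a coding gene, the antisense features held 67.8 to 86.5% in a library, with a median over libraries of 81.2%. The antisense feature was the higher of a pair in 65.1 to 76.8% of the pairs. Features opposite coding exons made up 17.8% of the annotated exon length and 44.7 to 78.2% of the counts outside rRNA repeats. Features with nothing annotated on the other strand made up 63.1% of exon length and 10.3 to 38.5% of those counts, which is called the own-strand share here. Values of a feature that overlaps a gene on the other strand are therefore uncertain under either reading. Among features named below, this also holds for CFLAR, TYRP1, VEGFA, EEF1B2, PSG5 and AC073508.2.

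The tests, gene lists and naming rule were set before the data were examined. The fit took all named features with enough counts (edgeR's filterByExpr by group, 10400 features) with TMM scaling. A single negative binomial fit of the 8 group means left 16 residual degrees of freedom, and robust quasi-likelihood F tests were made for 16 contrasts. Benjamini-Hochberg adjustment was applied per contrast at 0.05. This fit is called the all-feature fit. A strand-resolved fit was added after the data were seen, with 4179 coding genes. Of these, 1278 were read through the feature opposite their exons, where that feature held at least 3 times the mean count of the gene's own entry, and 2901 were read from their own entry, where nothing was annotated opposite. The 2 kinds of readout had separate offsets, so strand-resolved CPM are relative to counts of the same kind only. If counts lie on the opposite strand, own entries of the 2901 genes hold the smaller part of their reads. In 788 genes that have both readouts, fold changes from the opposite feature and from the own entry correlated with Pearson's r of 0.0483 to 0.337 in the 6 comparisons with DMSO, and 0.5305 between the lines with DMSO. Of 10 of these genes called with torin 2 in CH-157MN through the opposite feature, 50.0% had the same sign in the own entry, so strand-resolved values are uncertain. Some host features are coding genes themselves, among them SLC4A5 for MTHFD2, BEST1 for FTH1, CPM for MDM2, SLC26A10 for B4GALNT1 and SMPD4 for MZT2B, and such values are uncertain. The common dispersion was 0.123 in the all-feature fit and 0.0643 in the strand-resolved fit. Fold changes are log2 values with standard errors, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named.

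Gene lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over all lists of at least 5 tested genes and all contrasts together. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. Of 512 pairs of list and contrast, 123 passed in the all-feature fit. With an estimated correlation 0 passed by camera, where 28 had an unadjusted p under 0.05, and 14 passed by fry. In the strand-resolved fit 85 of 496 pairs passed, 27 with an estimated correlation and 143 by fry. Of the 85, 49 were also called in the all-feature fit in the same direction and 0 were called there in the opposite direction, by camera in both fits, and 155 strand-resolved pairs had an unadjusted p under 0.05. Both fits draw on the same counts, so calls of a list or gene in both are not independent of each other.

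Genes were named by a fixed rule: protein-coding genes past the threshold with a mean log2 CPM of at least 2, the 10 highest and 10 lowest fold changes against DMSO where all 3 treated libraries lay beyond all 3 control libraries, 5 and 5 for other contrasts, and up to 4 members of each called list in its direction and 2 against it. A few genes fixed in advance, NF2 among them, could be named in any case, and the text could leave out members of this set. Some genes that the rule names are not reported here. The rule was applied to the strand-resolved fit after the data were seen. Which of the genes named by the rule are printed was chosen after their values were seen, with preference for calls kept in every alternative. A fold against a group at 0 is a lower bound, set against a floor of 3 counts over the group. Intervals of shares are 95% Wilson intervals. Intervals and floors cover counting error only.

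Deviations of libraries with the same replicate number from their group means were correlated to see whether the numbers pair them. Of all pairs of groups within a line, only torin 2 and the combination in CH-157MN had all 3 correlations over 0.1, over all features (0.248, 0.12 and 0.118), so the blocked count is given beside that comparison. In strand-resolved values these were 0.213, 0.0709 and 0.119. The pairing comes from the values, since the labels give only numbers. Alternatives chosen in advance were the replicate number as a block, RLE and upper-quartile scaling, DESeq2, no filter, a filter of 5 CPM in 3 libraries, effective length offsets, a separate fit per line, limma on log2(TPM + 0.1), at least 2-fold change, and leaving out each library in turn. Alternatives chosen after seeing the data were the strand-resolved fit with its own block, scaling and leave-one-out settings, the own-strand share as a covariate, leaving out 3 libraries that stood apart, and leaving out the rRNA repeat features. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

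The test steps were tried on simulated counts with 200 changed genes. For digitoxin in CH-157MN, the all-feature step on 10400 features found 2.99% of genes changed 2-fold and 37.9% of those changed 4-fold, and it called 1 of 10200 unchanged features. The strand-resolved step on 4179 genes found 16.4% and 62.1% for that comparison and called 1 of 3979 unchanged genes. For the combination in IOMM-Lee the all-feature step found 7.46% and 40.9% at those sizes, and the strand-resolved step found 34.3% and 77.3%, with 3 of 10200 unchanged features and 5 of 3979 unchanged genes called. Unchanged groups against shared controls were simulated 20 times for the overlap of single agents and combination. All simulated counts were drawn for each gene apart, without the differences in own-strand share between whole libraries. In the real libraries 1 mixed split of IOMM-Lee digitoxin and combination libraries called 2123 features, so the rates of false calls hold only for libraries without such differences.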

Results

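Steady-state transcript levels were measured by RNA sequencing in CH-157MN and IOMM-Lee, 2 established lines derived from malignant tumours of the meninges. Each line was kept for 24 h with DMSO, with 78 nM digitoxin, with 2 nM torin 2, or with both. Digitoxin is a cardiac glycoside that blocks the Na+/K+-ATPase, the sodium pump, and torin 2 is an ATP-competitive inhibitor of the kinase mTOR. Each of the 8 groups had 3 libraries. Total expected counts ranged from 920885 to 4053509 per library, with a median of 2999490, far below the read depth that the labels state. A gene with 0 counts in 1 library could still lie below 0.740 to 3.26 CPM of all counts, rRNA repeats included, the level of 3 counts. Strand-resolved CPM are relative to counts of 1 kind of readout only, so 3 counts give a higher CPM there.

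The RNA content differed between libraries. Entries for rRNA repeats (FP671120.3, FP236383.2 and FP236383.3) held 71.1 to 87.3% of the counts in 22 libraries. The other 2 were CH-157MN DMSO replicate 1, with 3.77% (95% Wilson interval 3.73 to 3.81), and IOMM-Lee digitoxin replicate 3, with 4.47% (4.43 to 4.51). Without these entries 430340 to 1028773 counts per library were left, with a median of 585380. CH-157MN torin 2 replicate 1 had the highest own-strand share, 38.5%, against a median of 21.6%. The share followed torin 2 in CH-157MN, at 38.5, 25.2 and 25.7% against 11.3 to 23.9% in the other libraries of that line. CH-157MN DMSO replicate 1, IOMM-Lee digitoxin replicate 3 and CH-157MN torin 2 replicate 1 stood apart from the rest, and counts were also taken without them. Abundant coding genes often had fewer counts than the antisense feature opposite them, as AC006064.4 with a mean of 10090 counts opposite GAPDH with 567, and BEST1 with 11230 opposite FTH1 with 396. Gene values below are strand-resolved unless all features are named. Among others, ASNS, AARS, HSPH1, HSPB1, CYR61, EIF5, IGF1R, IL11, COL13A1, PSG4 and PSG9 were read from their own entries. If counts lie on the opposite strand, such entries hold the smaller part of the reads of a gene, so these values are uncertain. Over all features, the median fold change of all genes was 0.15 for torin 2 in CH-157MN, and in the strand-resolved fit it lay between −0.02 and 0.03 in every contrast.

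**Figure D1:**
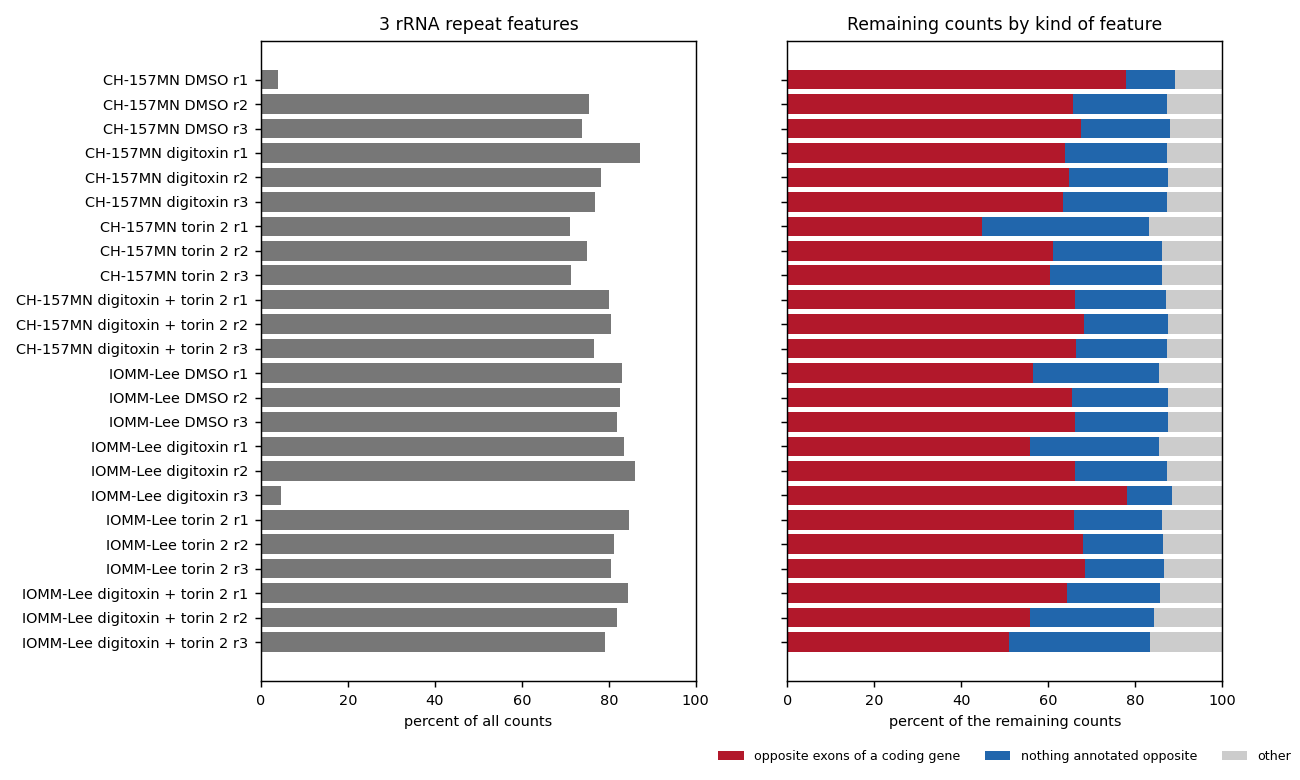
Bars give, for each of the 24 libraries, the percent of all expected counts on the 3 rRNA repeat features (left) and the split of the remaining counts by kind of feature (right). CH-157MN DMSO r1 and IOMM-Lee digitoxin r3 hold 3.77% and 4.47% rRNA repeat counts against at least 71.1% elsewhere, and CH-157MN torin 2 r1 holds the largest share on features with nothing annotated opposite, 38.5%.

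To ask what sodium pump inhibition alone changed in CH-157MN, digitoxin was compared with DMSO. BCAR3, an adaptor of adhesion signalling, was higher by 1.05 ± 0.18 (log2 fold change ± SE; adjusted p = 0.00445). PSG4, a pregnancy-specific glycoprotein, was higher by 2.49 ± 0.43 (adjusted p = 0.00972), the peptidase MME by 0.99 ± 0.21 (0.0341) and the organic anion transporter SLCO4A1 by 0.82 ± 0.16 (0.0155). UPF1, the helicase of nonsense-mediated decay, was lower (−1.29 ± 0.27, adjusted p = 0.0357). PSG4 (ENSG00000243137.7, chromosome 19, 43192702 to 43207299) has near-identical paralogs, so its counts are uncertain. DNA replication genes, which copy the genome in S phase, fell as a list (camera adjusted p = 0.019; 20 genes, median −0.33), and 2 members passed adjusted over the list alone and 0 over all genes, by edgeR. That adjusted p was 0.0648 with an estimated correlation. Clustered histone genes, whose mRNAs mostly lack a poly(A) tail, rose (adjusted p = 0.0198; 9 genes, median 0.69), and ribosomal protein genes fell (adjusted p = 0.0148; 49 genes, median −0.17). With an estimated correlation these adjusted p were 0.202 and 0.485, and without the 3 libraries that stood apart they were 0.512 and 0.111. The calls numbered 5 of 4179 genes, 4 of them higher, and 2 of 10400 features, PSG4 higher and AC073508.2 lower (−2.78 ± 0.47), where DESeq2 called 5, 4 of them higher. The 5 became 0 without digitoxin replicate 3, 1 without DMSO replicate 2, 2 without digitoxin replicate 1 or 2 and 3 without DMSO replicate 3. The 2 became 0 without DMSO replicate 1 or digitoxin replicate 3 and 1 without digitoxin replicate 1 or 2.

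Torin 2 against DMSO in CH-157MN addressed the response to mTOR inhibition alone. SLC7A11, the cystine and glutamate exchanger, fell from 198 ± 40.7 CPM with DMSO to 37.7 ± 7.92 with torin 2 (SD, n = 3; −2.37 ± 0.30, adjusted p = 6.92e-06). DDIT4, a stress-induced inhibitor of mTOR complex 1, fell from 1206 ± 189 to 339 ± 34.6 CPM (−1.83 ± 0.18, adjusted p = 5.44e-08). The glutamine transporter SLC1A5 (−0.76 ± 0.12, 0.000575) and PYCR1, an enzyme of proline synthesis (−1.12 ± 0.24, 0.0164), were also lower. SLC7A11 (ENSG00000151012.13, chromosome 4, 138164097 to 138242349, minus strand) was read through SLC7A11-AS1, and DDIT4 (ENSG00000168209.4, chromosome 10, 72273920 to 72276036, plus strand) through DDIT4-AS1. All 4 belong to the list of ATF4 targets and amino acid supply, genes of amino acid synthesis, transport and tRNA charging that the stress factor ATF4 induces. The list fell (adjusted p = 5.55e-08, and 0.0133 with an estimated correlation), with a median of −0.51 over 22 genes and 4 above 0. Of its members, 5 fell over all genes, and 8 fell and 1 rose adjusted over the list alone. NRF2 targets, antioxidant genes, fell (12 genes, adjusted p = 0.0189, and 0.0733 with an estimated correlation), 3 of them over all genes and 3 adjusted over the list alone, such as NQO1 (−0.81 ± 0.17, 0.016) and PRDX1 (−0.57 ± 0.14, 0.0377). Mitochondrially encoded genes fell (13 genes, median −0.65, adjusted p = 0.000128), with 0 members over all genes and 4 adjusted over the list alone, by edgeR. All mitochondrially encoded genes were read from their own entries, and the fall is relative to own-strand counts. Their share of counts outside rRNA repeats was 4.71 to 5.85% with torin 2 and 2.90 to 5.63% with DMSO. Mitosis genes rose (25 genes, median 0.86, adjusted p = 0.000257), with 0 members past either adjustment, by edgeR. With an estimated correlation the adjusted p of the mitochondrially encoded and mitosis lists were 0.353 and 0.236. Torin 2 replicate 1 had an own-strand share of 38.5%, and with that share as a covariate the adjusted p of the mitosis list was 0.29. The calls of PYCR1, NQO1 and PRDX1 were lost in at least 1 alternative.

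The torin 2 effect in CH-157MN had 47 calls over all features, 11 higher and 36 lower, and 33 of the 36 were features opposite coding exons. There, SAMD11 was lower (−1.80 ± 0.42), but its entry lies opposite exons of NOC2L and may hold NOC2L reads, so this value is uncertain. The matrix genes FN1 (1.48 ± 0.35) and TGFBI (1.70 ± 0.38) and the elongation factor EEF1B2 (1.91 ± 0.45) were higher. Each of these 4 genes had an adjusted p of 0.0488. All 4 calls were lost with effective length offsets, with limma on TPM and with the own-strand share as a covariate. Effective length offsets gave 3 calls, and DESeq2 made 1090. The strand-resolved fit also called 47, 21 higher and 26 lower. The count of 47 features became 3 without DMSO replicate 1 or without any 1 torin 2 library, 855 without DMSO replicate 2 and 198 without DMSO replicate 3. The count of 47 genes became 8 without DMSO replicate 1, 9 without torin 2 replicate 1, 71 without torin 2 replicate 2 and 100 without DMSO replicate 2, and without the 3 libraries that stood apart 2 features and 5 genes were called.

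Whether both agents together changed more or other genes was asked by comparing the combination with DMSO. In CH-157MN, SLC7A11 (47.6 ± 18.4 CPM; −2.05 ± 0.29, adjusted p = 5.39e-05) and DDIT4 (329.9 ± 63.9 CPM; −1.87 ± 0.18, 3.8e-08) were again lower than with DMSO. GAS6, the ligand of the AXL receptor kinase (1.39 ± 0.18, 1.15e-05), BCAR3 (1.02 ± 0.18, 0.000837), MME (1.24 ± 0.21, 0.000577), the transmembrane collagen COL13A1 (2.21 ± 0.38, 0.000948) and PSG4 (3.12 ± 0.43, 0.000102) were higher. XAF1, an interferon-induced regulator of apoptosis (−2.14 ± 0.34, 0.000263), B4GALNT1, a ganglioside synthase (−1.22 ± 0.21, 0.000837), and PSMC1, a proteasome ATPase (−0.59 ± 0.12, 0.00509), were lower. The ATF4 list fell (adjusted p = 1.93e-08, and 0.0104 with an estimated correlation; median −0.63), 3 of 22 genes over all genes and 5 adjusted over the list alone. Cytosolic heat shock genes, chaperones under the factor HSF1, fell (adjusted p = 1.17e-05, and 0.00421 with an estimated correlation), with 0 of 13 fold changes above 0, 0 members past the test over all genes by edgeR and 6 adjusted over the list alone. NRF2 targets fell too (adjusted p = 0.00295, and 0.0308 with an estimated correlation; 1 member over all genes and 3 adjusted over the list alone). Immediate early genes and targets of the coactivator YAP rose (adjusted p = 0.00124 and 0.00153), but with an estimated correlation the adjusted p were 0.0676 and 0.0648. The interferon response list fell (8 genes, adjusted p = 0.0218) and antigen presentation genes rose (7 genes, 0.0481), and with an estimated correlation these adjusted p were 0.0934 and 0.127. Among interferon genes, BST2 had 0 counts in both groups. OAS3 had 2 counts with the combination and 7 with DMSO, each over 3 libraries, so the fall of the interferon list is uncertain. The calls were 28 genes, 18 higher, and 7 features, 4 higher: PSG4, PSG5, PSG9 and COL13A1, against SLC7A11-AS1, DDIT4-AS1 and PRAL, which lies opposite XAF1. DESeq2 called 20 features, 14 of them higher. The 28 became 18 without DMSO replicate 1, 16 without combination replicate 2 and 14 without combination replicate 3. The 7 became 1 without DMSO replicate 1 or combination replicate 2, 2 without combination replicate 1 or 3 and 4 without DMSO replicate 2.

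The combination was then set against each agent in CH-157MN to see what the second agent added. Against digitoxin, SLC7A11 (−2.05 ± 0.30, adjusted p = 0.00014) and DDIT4 (−1.35 ± 0.18, 8.62e-05) were lower, and VIM, the intermediate filament vimentin (0.54 ± 0.09, 0.000875), was higher. The ATF4 list fell (adjusted p = 1.87e-10, and 0.00494 with an estimated correlation), 2 members over all genes and 6 adjusted over the list alone, NRF2 targets fell (adjusted p = 3.42e-05, and 0.00494 with an estimated correlation), 1 over all genes and 3 adjusted over the list alone, and heat shock genes fell (adjusted p = 0.00472, and 0.0395 with an estimated correlation; 13 of 13 fold changes below 0, 0 members past either adjustment by edgeR). Of 4179 genes 6 were called, 4 higher, and of 10400 features only AL133346.1 (2.68 ± 0.49, adjusted p = 0.0371), opposite the YAP target CTGF, named here after its value was seen. The 1 became 0 without any 1 digitoxin library or without combination replicate 1 or 2. Against torin 2, PSG1 (3.43 ± 0.65, adjusted p = 0.00474), PSG9 (3.11 ± 0.58, 0.00738) and the immediate early gene IER3 (0.74 ± 0.14, 0.00474) were higher, and mitosis genes fell (25 genes, median −0.73, adjusted p = 0.000207, and 0.234 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone by edgeR. Immediate early genes rose (adjusted p = 0.000555, and 0.0559 with an estimated correlation), 1 over all genes and 4 adjusted over the list alone. The calls were 47 genes, 35 higher, and 7 features, 6 higher, among them PSG4 (2.12 ± 0.40), PSG5 (2.11 ± 0.42) and TNFSF8 (3.02 ± 0.60), while the initiation factor EIF5 was lower (−1.94 ± 0.39). The 47 genes became 8 without torin 2 replicate 1, and 19 and 20 without combination replicates 2 and 3, and none of the named genes kept its call without torin 2 replicate 1. The 7 features became 0 without torin 2 replicate 1 or 2 or any 1 combination library and 1 without torin 2 replicate 3, and with the replicate number as a block they became 4, without TNFSF8 and EIF5 (adjusted p = 0.0532 for both) and PSG9 (0.0763). DESeq2 called 92, 61 of them higher, but most calls were lower with no filter (28 higher, 50 lower) and with a separate fit per line (49 higher, 103 lower).

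The interaction asked whether the joint effect in CH-157MN departed from the sum of the single effects on the log scale. Mitosis genes were below that sum as a list (median −1.13, adjusted p = 4.14e-05, and 0.191 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone by edgeR. By edgeR 0 features and 0 genes were called, with 1943 and 479 at an unadjusted p under 0.05, where DESeq2 called 3 features and limma 0.

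Digitoxin against DMSO in IOMM-Lee addressed sodium pump inhibition alone in the other line. SLC7A11 rose from 178 ± 16.1 to 587 ± 56.1 CPM (SD, n = 3; 1.72 ± 0.24, adjusted p = 2.74e-05), DDIT4 from 474 ± 50.5 to 1190 ± 295 CPM (1.33 ± 0.18, 1.37e-05) and SLC1A5 from 2855 to 6057 CPM (1.09 ± 0.12, 5.69e-07). MTHFD2, an enzyme of mitochondrial folate metabolism, rose by 0.83 ± 0.15 (0.00155). All 22 members of the list had fold changes above 0 (median 0.85, adjusted p = 2.72e-17, and 0.000538 with an estimated correlation). Of these, 5 passed over all genes and 12 adjusted over the list alone. NRF2 targets rose (12 genes, median 0.43, adjusted p = 4.14e-05, and 0.00494 with an estimated correlation), 3 over all genes and 5 adjusted over the list alone, including FTH1, the ferritin heavy chain (0.52 ± 0.09, 0.000366). Targets of p53 rose (11 genes, median 0.61, adjusted p = 0.0011, and 0.0178 with an estimated correlation), where 1 member passed either adjustment, MDM2 (0.61 ± 0.14, 0.0164), the ubiquitin ligase that holds p53 down. Ribosomal protein genes (median 0.27, adjusted p = 7.29e-05) and YAP targets (median 0.38, 0.0058) rose, with adjusted p of 0.266 and 0.0922 with an estimated correlation. CYR61, a secreted matrix protein and YAP target, rose from 1110 ± 274 to 2341 ± 432 CPM (1.07 ± 0.18, 0.00033), and the neurotrophin BDNF (1.88 ± 0.34, 0.00139) and RAB11FIP1, a factor of endosome recycling (1.66 ± 0.26, 0.000264), rose. EIF5 (ENSG00000100664.10, chromosome 14, 103333544 to 103345025) fell (−2.80 ± 0.34, 1.87e-06), and so did CAVIN3, a caveolar coat protein (−1.83 ± 0.36, 0.00309), and RCAN3, a regulator of calcineurin (−1.84 ± 0.32, 0.000759).

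Digitoxin in IOMM-Lee gave 80 called genes, 50 higher, and 16 called features, 11 higher, among them EIF5 (−2.84 ± 0.42, adjusted p = 0.000841), CFLAR, an inhibitor of death receptor signalling (1.96 ± 0.36, 0.00938), and TYRP1, an enzyme of melanin synthesis (2.59 ± 0.55, 0.0302). With effective length offsets 15 of 16 features were higher, and with upper-quartile scaling 34 of 80 genes were. The 80 became 140 without digitoxin replicate 1, 26 without DMSO replicate 2, 43 without DMSO or digitoxin replicate 3 and 47 without DMSO replicate 1. The calls of MDM2 and of these features were lost in at least 1 alternative. CFLAR and TYRP1 overlap a feature on the other strand, so their values are uncertain. The 16 became 155 without digitoxin replicate 1, 9 without replicate 2, 4 without replicate 3 and 3 without any 1 DMSO library.

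Torin 2 alone in IOMM-Lee was again set against DMSO. SLC7A11 fell to 44.2 ± 22.98 CPM (−1.97 ± 0.29, adjusted p = 0.000103) and DDIT4 to 161 ± 35.2 CPM (−1.55 ± 0.19, 7.08e-06). The ATF4 list fell (median −0.67, adjusted p = 1.87e-10, and 0.00494 with an estimated correlation), 1 of 22 fold changes above 0, 4 members over all genes and 6 adjusted over the list alone. Vimentin (VIM, 0.99 ± 0.09, 3.31e-09), TIMP2, an inhibitor of matrix proteases (0.75 ± 0.14, 0.00269), and CYR61 (2416 ± 338 CPM; 1.12 ± 0.18, 0.000235) rose. Extracellular matrix genes rose as a list (23 genes, median 0.57, adjusted p = 0.0023, and 0.0186 with an estimated correlation), 2 over all genes and 3 adjusted over the list alone. Ribosomal protein genes rose (median 0.36, adjusted p = 1.11e-09, and 0.105 with an estimated correlation), 3 over all genes and 11 adjusted over the list alone, such as RPL28 (0.78 ± 0.14, 0.00212). PDK2, a kinase that restrains pyruvate oxidation, rose (1.18 ± 0.21, 0.0016). Mitosis genes (median −0.53, adjusted p = 0.00138) and heat shock genes (median −0.42, 0.00971) fell, but with an estimated correlation these adjusted p were 0.287 and 0.0559. YAP targets, immediate early genes and antigen presentation genes rose (adjusted p = 0.00458, 0.0131 and 0.035), and with an estimated correlation the adjusted p were 0.0901, 0.137 and 0.105. The calls were 39 genes, 28 higher, and 1 feature, AL133346.1 opposite CTGF (2.58 ± 0.47, adjusted p = 0.0382), where DESeq2 called 5, 4 of them higher. The 39 became 15 without torin 2 replicate 3, 21 to 24 without any other torin 2 or DMSO library, and 136 without the 3 libraries that stood apart. The 1 was lost without DMSO replicate 1 or 2 or torin 2 replicate 2.

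In IOMM-Lee the combination was compared with DMSO. SLC7A11 (542 ± 94.8 CPM; 1.61 ± 0.24, adjusted p = 3.97e-05), SLC1A5 (0.82 ± 0.12, 2.76e-05), MTHFD2 (1.11 ± 0.15, 1e-05) and ASNS, asparagine synthetase (from 11.8 ± 20.5 to 262 ± 66.9 CPM; 4.02 ± 0.76, 0.000939), rose. With DMSO, ASNS was at 35.4 CPM in replicate 1 and at 0 CPM in replicates 2 and 3, so its fold change is uncertain. All 22 members of the ATF4 list had fold changes above 0 (median 1.01, adjusted p = 2.82e-17, and 0.000538 with an estimated correlation), with 9 past the test over all genes and 20 adjusted over the list alone. Over all features the list rose as well (36 entries, median 1.04, adjusted p = 3.37e-15, and 0.247 with an estimated correlation). All 49 ribosomal protein genes had fold changes above 0 (median 0.53, adjusted p = 1.53e-15, and 0.0429 with an estimated correlation), 12 over all genes and 24 adjusted over the list alone, among them RPL13A (0.77 ± 0.15, 0.00108) and RPL23A (0.50 ± 0.10, 0.00196). Heat shock genes fell (median −0.87, adjusted p = 1.54e-08, and 0.000538 with an estimated correlation), 6 of 13 over all genes and 8 adjusted over the list alone. HSPH1, a large chaperone of the HSP110 class (ENSG00000120694.19, chromosome 13, 31134974 to 31162388, minus strand), fell from 1592 ± 170 to 587 ± 91.7 CPM (−1.45 ± 0.21, 2.38e-05), the small chaperone HSPB1 by 1.37 ± 0.23 on the log2 scale (0.000175) and the co-chaperone STIP1 by 1.14 ± 0.20 (0.000357). HSPH1 and HSPB1 were read from their own entries. YAP targets rose (11 of 11 fold changes above 0, adjusted p = 1.81e-05, and 0.0161 with an estimated correlation), 2 over all genes and 5 adjusted over the list alone, with CYR61 at 3010 ± 176 CPM (1.43 ± 0.17, 1.18e-06). Of 5 measured cholesterol synthesis genes, 2 fell over all genes and 3 adjusted over the list alone, HMGCS1 (−1.34 ± 0.21, 6.67e-05) among them (list adjusted p = 0.00145, and 0.0647 with an estimated correlation). Immediate early genes rose (adjusted p = 0.00803, and 0.105 with an estimated correlation) with members that went both ways: DUSP6, a phosphatase of ERK (1.19 ± 0.14, 1.18e-06), was higher, and FOSL1 (−0.69 ± 0.18, 0.018) and JUN (−0.86 ± 0.25, 0.0364), subunits of AP-1, were lower, with calls lost in at least 1 alternative.

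Further calls for the combination in IOMM-Lee were BDNF (2.93 ± 0.33, adjusted p = 4.64e-07), the cytokine IL11 (2.66 ± 0.59, 0.00401) and the receptor kinase IGF1R (2.85 ± 0.51, 0.000529), all higher, and EIF5 (−2.72 ± 0.32, 7.5e-07) and the oxygen-sensing hydroxylase EGLN2 (−2.29 ± 0.50, 0.00401), both lower. Over all features, VEGFA, the vascular growth factor (2.08 ± 0.37, 0.00357), TYRP1 (3.06 ± 0.54, 0.00353) and IGF1R (2.99 ± 0.54, 0.00416) were higher, with calls lost in at least 1 alternative. VEGFA and TYRP1 overlap a feature on the other strand, so their values are uncertain. In total 237 genes were called, 97 higher and 140 lower, and 46 features, 24 higher and 22 lower. With upper-quartile scaling 28 features were higher and 35 lower, and with RLE scaling 28 were higher and 21 lower. The 237 became 112 and 138 without combination replicates 3 and 2, and 122 and 133 without DMSO replicates 2 and 3. The 46 became 9 and 10 without DMSO replicates 2 and 3, 14 without combination replicate 2 or 3, and 442 without the 3 libraries that stood apart.

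**Figure D2:**
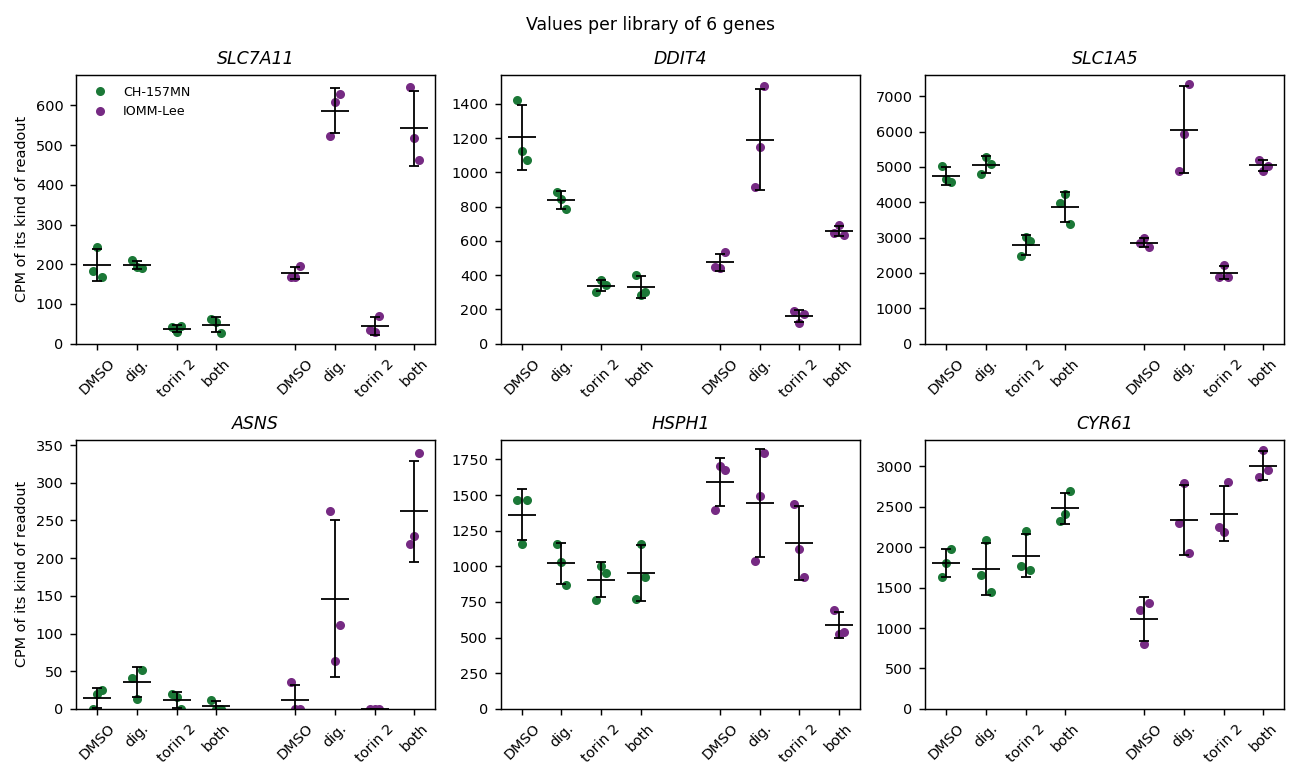
Points are the 3 libraries of each group, bars give the mean and SD (n = 3), and the vertical axis is CPM of the gene's kind of readout, from 0. ASNS, HSPH1 and CYR61 were read from their own entries, and SLC7A11 and DDIT4 through the feature opposite. SLC7A11 lies at 198 and 178 CPM with DMSO in CH-157MN and IOMM-Lee, falls with torin 2 in both lines, and is at 47.6 and 542 CPM with both agents.

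To see what torin 2 added to digitoxin in IOMM-Lee, the combination was compared with digitoxin. Heat shock genes fell (median −0.78, adjusted p = 6.46e-07, and 0.0015 with an estimated correlation), 4 of 13 over all genes and 7 adjusted over the list alone, with HSPH1 at −1.30 ± 0.21 (0.000436). EEF2, the translocase of peptide elongation (1.01 ± 0.11, 2.02e-07), PABPC1, the poly(A)-binding protein (0.65 ± 0.12, 0.00195), and RPL12 (0.97 ± 0.19, 0.00261) rose. Ribosomal protein genes rose (adjusted p = 7.42e-06), 4 over all genes and 7 adjusted over the list alone. Translation factors rose too (adjusted p = 0.00102), with 2 higher over all genes, and 4 higher and 1 lower adjusted over the list alone. With an estimated correlation these adjusted p were 0.229 and 0.105. TEX19 (1.57 ± 0.25, 0.000436) and the lysosomal enzyme IDUA (1.97 ± 0.36, 0.00195), read through the coding gene SLC26A1, were higher. The calls were 86 genes, 26 higher and 60 lower, or 28 higher and 39 lower with upper-quartile scaling. Over all features edgeR called 0, with 1538 at an unadjusted p under 0.05, where DESeq2 called 268 and limma 0. The 86 became 230 without digitoxin replicate 1, 41 without digitoxin replicate 3, and 44 and 37 without combination replicates 2 and 3. The 0 became 982 without digitoxin replicate 1 and 1 without digitoxin replicate 2.

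The comparison with torin 2 asked in turn what digitoxin added. SLC7A11 (3.58 ± 0.28, adjusted p = 1.09e-10), DDIT4 (2.02 ± 0.19, 5.29e-09), MTHFD2 (1.87 ± 0.16, 4.05e-10) and SLC1A5 (1.33 ± 0.12, 3.2e-09) were higher with both agents. ASNS had 0 counts with torin 2 and was at least 25.4-fold higher. All 22 members of the ATF4 list were higher in fold change (median 1.65, adjusted p = 5.28e-39, and 8.3e-06 with an estimated correlation), 19 over all genes and 20 adjusted over the list alone. Over all features 19 of 36 entries passed over all genes and 26 rose and 1 fell adjusted over the list alone (adjusted p = 6.77e-29, and 0.101 with an estimated correlation), with PHGDH, the first enzyme of serine synthesis, at 3.11 ± 0.48 (0.000302). NRF2 targets rose (adjusted p = 0.000621, and 0.014 with an estimated correlation), with 4 higher and 1 lower over all genes, and 6 higher and 1 lower adjusted over the list alone. TXNRD1, a thioredoxin reductase, was at 2.23 ± 0.45 (0.00185). Extracellular matrix genes fell (adjusted p = 0.0173, and 0.062 with an estimated correlation), 6 over all genes and 7 adjusted over the list alone, including the collagen VI chains COL6A1 (−2.36 ± 0.37, 0.000235) and COL6A3 (−2.11 ± 0.37, 0.000388). Heat shock genes fell (adjusted p = 0.0058, and 0.0429 with an estimated correlation), 3 over all genes and 3 adjusted over the list alone, HSPB1 (−1.44 ± 0.23, 0.000115) among them. The calls were 256 genes, 100 higher and 156 lower, and 142 features, 67 higher and 75 lower. With RLE scaling 84 features were higher and 65 lower, and with upper-quartile scaling 72 were higher and 83 lower, so the larger side depended on the scaling. The 256 became 142, 123 and 120 without torin 2 replicates 1, 2 and 3, and 104 and 100 without combination replicates 2 and 3. The 142 features became 55, 41 and 43 without torin 2 replicates 1, 2 and 3, 306, 31 and 28 without combination replicates 1, 2 and 3, and 1118 without the 3 libraries that stood apart.

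For the interaction in IOMM-Lee, the ATF4 list lay above the sum of the single effects (21 of 22 fold changes above 0, median 0.84, adjusted p = 3.05e-09, and 0.0081 with an estimated correlation), 2 over all genes and 6 adjusted over the list alone. The 4 called genes were SLC7A11 (1.86 ± 0.37) and MTHFD2 (1.04 ± 0.22) above the sum and MZT2B, read through the coding gene SMPD4 (−1.08 ± 0.23), and ARHGDIA (−0.73 ± 0.15) below it, each with an adjusted p of 0.0399. The 4 became 54 without digitoxin replicate 1, 2 without digitoxin or combination replicate 3, 1 without torin 2 replicate 3, and 0 without DMSO replicate 2 or 3, digitoxin replicate 2, torin 2 replicate 1 or 2, or combination replicate 1 or 2, and 2 with upper-quartile scaling. Over all features edgeR called 0, with 1417 at an unadjusted p under 0.05, where DESeq2 called 1 and limma 0, and 108 were called without digitoxin replicate 1, 1 without digitoxin replicate 3 and 1 without torin 2 replicate 1.

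**Figure D3:**
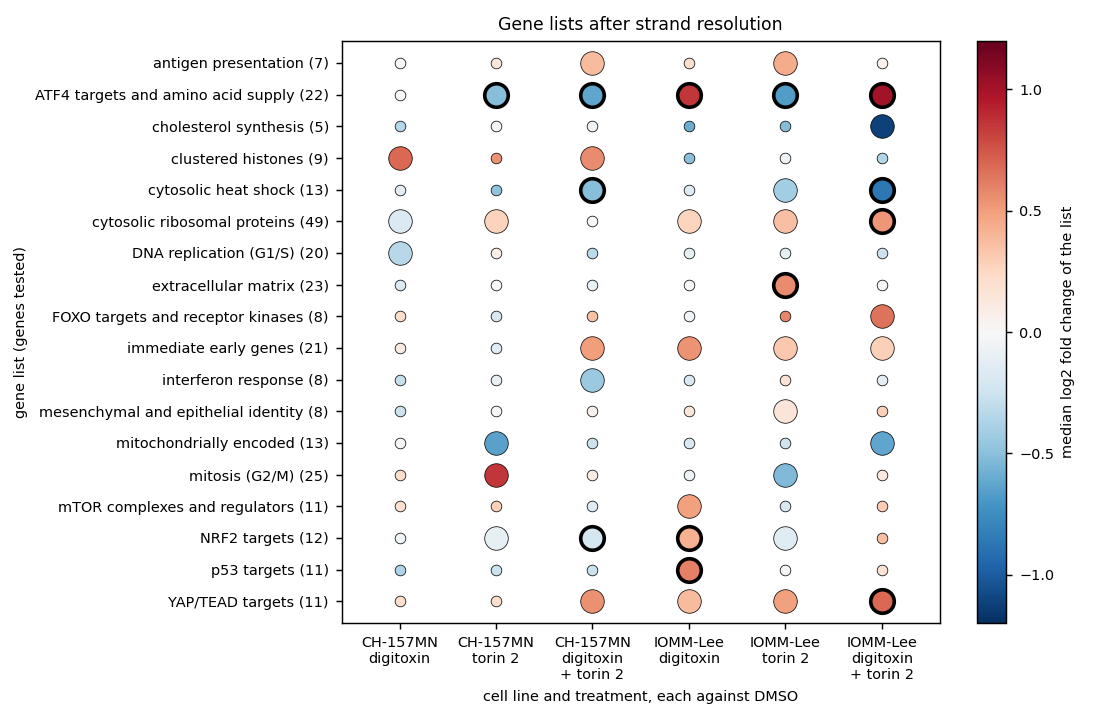
Each dot is 1 gene list in 1 comparison with DMSO, coloured by the median log2 fold change of the list (genes tested in parentheses). Large dots mark a camera adjusted p under 0.05 and thick outlines those also under 0.05 with an estimated correlation, and the ATF4 list has medians of −0.63 and 1.01 with both agents in CH-157MN and IOMM-Lee.

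Whether the lines differed in their response was tested directly as the difference of effects, IOMM-Lee minus CH-157MN. For the combination, all 22 members of the ATF4 list had positive differences (median 1.70, adjusted p = 2.27e-32, and 1.47e-05 with an estimated correlation), 9 over all genes and 16 adjusted over the list alone. SLC7A11 (3.65 ± 0.38, adjusted p = 1.85e-07), DDIT4 (2.34 ± 0.26, 2.82e-07), MTHFD2 (1.73 ± 0.22, 8.05e-06) and SLC1A5 (1.12 ± 0.17, 0.000161) were among the called members. For digitoxin the list also differed (median 1.09, 20 of 22 above 0, adjusted p = 2.42e-10, and 0.00494 with an estimated correlation), 5 over all genes and 7 adjusted over the list alone, and p53 targets differed (median 0.77, adjusted p = 0.000674, and 0.0143 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone by edgeR. For torin 2 the called genes were VIM (0.999 ± 0.12, 1.05e-05), PARP8 (3.77 ± 0.76, 0.0307) and AL157392.5 (−2.57 ± 0.48, 0.0178), and mitosis genes differed (median −1.57, adjusted p = 2.14e-07, and 0.116 with an estimated correlation), 0 over all genes and 11 adjusted over the list alone by edgeR. Of the 3 genes only VIM kept its call in every alternative of the strand-resolved fit. The differences numbered 27 genes for digitoxin, 3 for torin 2 and 34 for the combination. Over all features edgeR called 0 for digitoxin, 0 for torin 2 and 2 for the combination, with 1380 and 2478 at an unadjusted p under 0.05 for the single agents, where DESeq2 called 75, 497 and 15 and limma 1, 0 and 1. For digitoxin, the 27 became 88 and 11 without IOMM-Lee digitoxin replicates 1 and 3, 10 and 15 without CH-157MN digitoxin replicates 1 and 3, 15 without CH-157MN DMSO replicate 1 and 16 without IOMM-Lee DMSO replicate 2. The 0 features became 464 without IOMM-Lee digitoxin replicate 1, 12 and 5 without CH-157MN DMSO replicates 2 and 3, and 1 without any 1 IOMM-Lee DMSO library or digitoxin replicate 2. For torin 2, the 3 genes became 1 without CH-157MN torin 2 replicate 1 or IOMM-Lee torin 2 replicate 1 or 3, 8, 11 and 7 without CH-157MN DMSO replicates 1, 2 and 3, 16 and 13 without CH-157MN torin 2 replicates 2 and 3, and 10 without IOMM-Lee DMSO replicate 3. For the combination, the 34 became 22 without CH-157MN DMSO replicate 2, 21, 18 and 16 without CH-157MN combination replicates 1, 2 and 3, 20 and 15 without IOMM-Lee DMSO replicates 2 and 3, and 16 and 18 without IOMM-Lee combination replicates 2 and 3. The 2 features became 6 without IOMM-Lee combination replicate 1 and 1 without CH-157MN DMSO replicate 1, CH-157MN combination replicate 2 or 3, IOMM-Lee DMSO replicate 1 or 3 or IOMM-Lee combination replicate 3.

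The untreated lines were compared to describe their starting states. The collagen VI chains COL6A1 (ENSG00000142156.14, chromosome 21, 45981737 to 46005050; −7.33 ± 0.24, adjusted p = 5.13e-22) and COL6A3 (−5.07 ± 0.31) and fibronectin, FN1 (−4.05 ± 0.27, adjusted p = 6.43e-12), were lower in IOMM-Lee, while the basement membrane collagen COL4A1 was higher (4.69 ± 0.57, 9.02e-08). As a list, extracellular matrix genes were lower (median −3.26, adjusted p = 7.02e-21, and 3.6e-06 with an estimated correlation), 16 lower and 1 higher of 23 over all genes and 17 and 1 adjusted over the list alone. Genes of NF-kB and inflammatory mediators were lower (median −2.68, adjusted p = 2.77e-06, and 0.014 with an estimated correlation), 9 of 13 under either adjustment. The neutrophil-attracting chemokines CXCL1, CXCL5 and CXCL3 had 0 counts in IOMM-Lee and were at least 143-fold, 57.1-fold and 18.3-fold lower there. PAPPA, a protease of IGF-binding proteins, was at least 132.8-fold lower. Over all features, NF2, the tumour suppressor lost in many meningiomas (2.41 ± 0.45, adjusted p = 0.000149), and TERT, the telomerase catalytic subunit (3.15 ± 0.64, 0.00053), were higher in IOMM-Lee, and COL1A1 was lower (−5.38 ± 0.53). In all, 901 genes differed, 395 higher and 506 lower, and 1379 features, 527 higher and 852 lower.

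Calls shared by the lines were counted for each treatment. With torin 2, 2 genes rose and 8 fell in both, against 0.141 and 0.0684 expected from independent lists, SLC7A11, DDIT4 and SLC1A5 among those that fell. With the combination 6 rose and 4 fell in both, against 0.418 and 0.335 expected, and 2 went opposite ways. With digitoxin edgeR called 0 genes in both, with 383 and 556 genes at an unadjusted p under 0.05. Over all features the numbers shared were 0, 0 and 1 for digitoxin, torin 2 and the combination. Across 4179 genes, which are not independent replicates, fold changes of the lines correlated with Pearson's r of −0.04 for digitoxin, −0.11 for torin 2 and 0.14 for the combination (Spearman's rho −0.03, −0.12 and 0.16). Without the 3 libraries that stood apart 3 genes were called in both lines with torin 2, all lower, 16 went the same way with the combination (10 higher, 6 lower) and 2 with digitoxin (1 higher, 1 lower). Without them r was 0.0552, −0.00296 and 0.0694 (rho 0.109, 0.00273 and 0.0991), so the sign turned for digitoxin. Over all features r was −0.142, −0.228 and 0.141, and 0.0618, −0.0748 and 0.0684 without those libraries.

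How far single agents accounted for the combination was described by the overlap of calls, which share the DMSO libraries. In CH-157MN, 4 of the 28 genes called for the combination were also called with digitoxin and 8 with torin 2. Independent lists would share 0.0196 and 0.153, and as many top genes of unchanged groups simulated against the same controls shared 0.9 and 4.85. In IOMM-Lee it was 38 and 16 of 237, against 2.17 and 1.02 for independent lists and 23.8 and 14.4 in the simulation. Over all features it was 1 and 2 of 7 in CH-157MN (0.15 and 1.5 in the simulation) and 6 and 1 of 46 in IOMM-Lee (3.2 and 0.2). With 3 DMSO libraries per line the controls could not be parted into sets of at least 2, so part of the excess of these overlaps may come from the shared controls. Of the 237 genes, 91.6% had the same sign with digitoxin and 76.4% with torin 2, where unchanged groups simulated against the same controls gave 90.3 and 89.2%. Over all 4179 genes in IOMM-Lee the covariance of fold changes with the combination was 0.271 for digitoxin and 0.130 for torin 2, against 0.146 and 0.144 in the simulation. In CH-157MN it was 0.234 and 0.207 against 0.163 and 0.163. The sum of both single effects had a median ratio to the combined effect of 0.743 in IOMM-Lee and 1.02 in CH-157MN, against 1.05 and 0.9845 in the simulation.

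Lists without a strand-resolved call are also results. By camera at the preset correlation, no strand-resolved contrast called BCL2 family genes, which set the threshold of apoptosis, or genes of fatty acid synthesis, ribosome biogenesis, the endoplasmic reticulum stress response, nuclear-encoded oxidative phosphorylation, lysosome and autophagy, sodium, potassium and calcium handling, glycolysis, hypoxia, the proteasome or meningioma. Of these 176 pairs of list and contrast, 16 had an unadjusted p under 0.05, 0 passed with an estimated correlation and 26 passed by fry. By camera 6 pairs passed with the own-strand share as a covariate, and 5 without the 3 libraries that stood apart. These counts hold for the strand-resolved fit only. Over all features, the fit set in advance, 123 pairs passed by camera, and only 49 of them were also called strand-resolved. Calls of these lists over all features are not given here, so the lists may have calls there. Single members passed over all genes by edgeR 79 times in the 16 contrasts, 19 of them against DMSO. Markers of other cells could hardly be measured in the strand-resolved fit, with 2 endothelial, 1 epithelial and 1 leukocyte gene and no neural or glial gene.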

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

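The strand-resolved tests, the gene list tests in them, the regroupings and the tests of the ATF4 pattern were chosen only after the result was seen, while the differences over all features were planned. Each difference below was picked out because a test of the difference between the effects in the 2 lines (IOMM-Lee minus CH-157MN) passed, and values are log2 differences in the strand-resolved fit unless all features are named.

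For digitoxin the differences were 1.86 for DDIT4, 1.72 for SLC7A11, 1.58 for PYCR1, 0.99 for SLC1A5, 2.42 for SLC3A2, 0.62 for FTH1, 2.26 for RAB11FIP1, −2.25 for EIF5 and −1.83 for RCAN3. For torin 2 they were 1 for VIM, 3.77 for PARP8 and −2.57 for AL157392.5. For the combination they were 3.65 for SLC7A11, 2.34 for DDIT4, 1.73 for MTHFD2, 1.12 for SLC1A5, 2.59 for AARS, 2.60 for EPRS, 2.28 for BDNF, 0.52 for FTH1, −1.79 for HMGCS1, −1.92 for CAVIN3 and −3.28 for HIST1H2BK. Over all features, RPL12P14 (5.05) and SLC7A11-AS1 (3.75) differed for the combination.

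Of the gene lists, ATF4 targets (adjusted p = 2.42e-10), ribosomal protein genes (1.05e-06), p53 targets (0.000674) and NRF2 targets (0.0106) had higher and clustered histones (0.00078) lower effects of digitoxin in IOMM-Lee. With an estimated correlation the adjusted p were 0.00494, 0.191, 0.0143, 0.0598 and 0.0901 in that order, so ribosomal, NRF2 and histone calls were lost. Mitosis genes had a lower effect of torin 2 (adjusted p = 2.14e-07, and 0.116 with an estimated correlation). For the combination, ATF4 targets (2.27e-32), ribosomal protein genes (4.38e-11), NRF2 targets (0.000226) and mTOR complexes (0.035) had higher and clustered histones (0.000701) and cholesterol synthesis genes (0.00199) lower effects. With an estimated correlation the adjusted p were 1.47e-05, 0.0901, 0.01005, 0.102, 0.0903 and 0.0702 in that order, so only the ATF4 and NRF2 calls were kept. Histone mRNAs mostly lack a poly(A) tail, and the 2 libraries lowest in RNAs without a tail, CH-157MN DMSO replicate 1 (0.0980%) and IOMM-Lee digitoxin replicate 3 (0.236%), both lower the histone difference for digitoxin, and the first also that for the combination. Without the 3 libraries that stood apart the adjusted p of the histone list were 0.0441 and 0.0162, and HIST1H2BK kept its call. Without CH-157MN DMSO replicate 1 alone HIST1H2BK lost its call (−3.06, 0.0812). It also lost it without DMSO replicate 3 or combination replicate 1 or 3 in CH-157MN, and without DMSO replicate 1 or 3 or combination replicate 2 or 3 in IOMM-Lee.

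Counts also lay on entries outside the tests, and were picked out as signal in unused data. Entries named by a number summed to at most 49.3 counts, in CH-157MN torin 2 replicate 1, and spike-in entries to at most 6, in CH-157MN torin 2 replicate 2.

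The differences between lines were also counted after regrouping the libraries in 100 ways, the real one included. The number of regroupings was set to 100 after values with fewer had been seen. In the strand-resolved fit as many genes as the real 27 for digitoxin were called in 2 of 100, as many as 3 for torin 2 in 5 and as many as 34 for the combination in 6, with up to 29, 10 and 67 genes in the other regroupings. Over all features it was 100, 100 and 4 of 100 for the real 0, 0 and 2, with up to 225, 1 and 6 features elsewhere. For the interactions over all features it was 100 of 100 in both lines, with up to 1 feature in CH-157MN and 1460 in IOMM-Lee. In the strand-resolved fit it was 100 of 100 in CH-157MN, with up to 4 genes, and 7 of 100 for the 4 genes in IOMM-Lee, with up to 367. The regroupings with 29, 10, 67, 6, 1460 and 367 calls each kept 1 real pair of groups whole and mixed the other, so they hold drug effects and point to a structure of the samples. The regrouping with 225 features for digitoxin mixed both pairs and still called more than the real 0. Regroupings that hold drug effects do not measure chance alone, and a real count of 0 leaves nothing to test, so chance was not excluded for any of these counts.

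The ATF4 list was lower with torin 2 in both lines and higher with digitoxin and with the combination in IOMM-Lee. The own-strand share is argued against as the whole source, since with it as a covariate the largest adjusted p of the 4 calls was 1.56e-11. Without the 3 libraries that stood apart it was 3.26e-10, so those libraries did not account for the strand-resolved calls. With an estimated correlation between members it was 0.0133, by camera, which argues against correlated members in the strand-resolved fit only. Over all features 0 of 512 pairs of list and contrast passed camera with an estimated correlation, so correlated members stay open there. For digitoxin and the combination, a drug effect on these genes that differs between the lines may underlie the pattern, as a hypothesis found and tested on the same libraries. For torin 2 the list fell in both lines, and strand-resolved camera called no difference between the lines for it. Depth, replicate origin and the uncertain strand assignment stay open.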

How the results depend on the processing

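The covariate, the leaving out of 3 libraries, the leaving out of rRNA features and the strand-resolved fit were chosen only after the result was seen. In every alternative that tested them, 20 of 60 calls of named genes over all features and 100 of 188 strand-resolved ones were kept. Over all features, some calls were not tested with the filter of 5 CPM or with a separate fit per line. Of the calls of gene lists, 0 of 123 over all features and 27 of 85 strand-resolved ones were kept. The gene shares cover named genes only, and genes were printed with preference for calls kept in every alternative. These gene shares therefore do not measure how stable all calls were. Depth limits calls of genes with few counts, and the cause was not tested for any change below except where fewer libraries or genes entered.

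Calls over all features moved from the reported count as follows. Torin 2 in CH-157MN (47): 3 with a replicate block, 155 upper quartile, 1090 DESeq2, 473 no filter, 3 effective length, 1199 separate lines, 1 limma on TPM, 5 covariate, 2 without the 3 libraries, 328 without rRNA features. Digitoxin in CH-157MN (2): 5 DESeq2, 9 no filter, 6 separate lines, 0 limma, 30 covariate. Combination in CH-157MN (7): 20 DESeq2, 19 no filter, 4 effective length, 16 separate lines, 0 limma, 90 covariate, 19 without the 3 libraries. Combination against digitoxin in CH-157MN (1): 0 upper quartile, 2 no filter, 0 effective length, 0 limma, 18 covariate, 3 without the 3 libraries. Combination against torin 2 in CH-157MN (7): 4 replicate block, 16 RLE, 15 upper quartile, 92 DESeq2, 78 no filter, 21 strict filter, 0 effective length, 152 separate lines, 1 limma, 37 covariate, 31 without the 3 libraries, 16 without rRNA features. Interaction in CH-157MN (0): 3 DESeq2, 37 no filter, 9 separate lines. Digitoxin in IOMM-Lee (16): 64 DESeq2, 48 no filter, 10 separate lines, 6 limma, 184 covariate, 29 without the 3 libraries. Torin 2 in IOMM-Lee (1): 0 upper quartile, 5 DESeq2, 3 no filter, 0 effective length, 0 separate lines, 0 limma, 143 covariate, 67 without the 3 libraries, 0 without rRNA features. Combination in IOMM-Lee (46): 110 DESeq2, 15 effective length, 26 separate lines, 1 limma, 546 covariate, 442 without the 3 libraries. Combination against digitoxin in IOMM-Lee (0): 268 DESeq2, 79 no filter, 1 effective length, 85 covariate, 7 without the 3 libraries. Combination against torin 2 in IOMM-Lee (142): 267 DESeq2, 73 effective length, 13 limma, 277 covariate, 1118 without the 3 libraries. Interaction in IOMM-Lee (0): 1 DESeq2, 5 no filter, 3 covariate. Line difference for digitoxin (0): 4 RLE, 75 DESeq2, 111 no filter, 1 limma, 27 covariate, 3 without rRNA features. Line difference for torin 2 (0): 497 DESeq2, 177 no filter, 1 covariate. Line difference for the combination (2): 15 DESeq2, 11 no filter, 1 effective length, 1 limma, 114 covariate, 34 without the 3 libraries. The split moved too with DESeq2, to 7 of 15 higher for the last.

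Strand-resolved counts were 5, 47, 28, 6, 47 and 0 in CH-157MN (digitoxin, torin 2, combination, combination against digitoxin, against torin 2, interaction), 80, 39, 237, 86, 256 and 4 in IOMM-Lee, 27, 3 and 34 for the line differences and 901 between lines. Without the 3 libraries they were 6, 5, 37, 15, 32 and 0, then 81, 136, 402, 66, 499 and 5, then 13, 14 and 65, and 894. With the covariate they were 20, 8, 94, 20, 31, 0, 129, 112, 355, 83, 200, 2, 21, 3, 88 and 957. The interaction in IOMM-Lee was 0 with a block and 2 with upper quartile, and the line difference for torin 2 was 10 with RLE. Gene list calls (123) were 0 with an estimated correlation and 14 by fry, and 27 of 85 strand-resolved with an estimated correlation.

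Genes shared by the lines for digitoxin (0): 8 covariate, 7 strand-resolved covariate, 2 strand-resolved without the 3 libraries. For torin 2 (0): 4 covariate, 2 without the 3 libraries, 10 strand-resolved, 8 with its block, 5 with its covariate, 3 without the 3 libraries. For the combination (1): 38 covariate, 6 without the 3 libraries, 10 strand-resolved, 10 with its block, 37 with its covariate, 16 without the 3 libraries. Combination genes also called with digitoxin in CH-157MN (1): 2 block, 4 DESeq2, 5 no filter, 2 strict filter, 5 separate lines, 0 limma, 16 covariate, 2 without the 3 libraries, 4 strand-resolved, 5 strand-resolved without them. With torin 2 in CH-157MN (2): 6 DESeq2, 7 no filter, 8 separate lines, 0 limma, 8 strand-resolved. With digitoxin in IOMM-Lee (6): 20 DESeq2, 14 no filter, 2 separate lines, 1 limma, 115 covariate, 25 without the 3 libraries, 38 strand-resolved, 62 strand-resolved without them. With torin 2 in IOMM-Lee (1): 0 upper quartile, 2 DESeq2, 0 effective length, 0 separate lines, 0 limma, 78 covariate, 15 without the 3 libraries, 0 without rRNA features, 16 strand-resolved, 63 strand-resolved without them.

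Leaving out each library in turn gave, over all features and strand-resolved: digitoxin in CH-157MN 0 to 2 and 0 to 4, torin 2 3 to 855 and 8 to 100, combination 1 to 6 and 14 to 36, against digitoxin 0 to 1 and 4 to 8, against torin 2 0 to 1 and 8 to 67, interaction 0 to 1 and 0 to 1. In IOMM-Lee it gave 3 to 155 and 26 to 140, 0 to 1 and 15 to 24, 9 to 59 and 112 to 227, 0 to 982 and 37 to 230, 28 to 306 and 100 to 326, and 0 to 108 and 0 to 54. Line differences were 0 to 464 and 10 to 88, 0 to 0 and 1 to 16, and 1 to 6 and 15 to 32, and the lines with DMSO 952 to 1343 and 741 to 822.

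With the covariate, lists called over all features turned direction, at adjusted p of 0.66 (YAP targets, CH-157MN interaction), 0.965, 0.289 and 0.26 (heat shock, ribosomal and translation factor genes, line difference for torin 2), 0.0258 and 0.772 (ribosomal and translation factor genes, IOMM-Lee interaction) and 0.341 (mitosis, line difference for digitoxin). Medians of 0 lists over all features turned sign with RLE, 0 with upper quartile and 1 of 123 with effective length. The median of all features was 0.15 for torin 2 in CH-157MN, −0.11 for its interaction and −0.17 for the line difference for torin 2. With limma on TPM it was −0.75 for digitoxin and −0.69 for the combination in CH-157MN, −0.69 between lines, 0.44 for digitoxin in IOMM-Lee, and 1.17 and 0.83 for the line differences for digitoxin and the combination.

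Of 36 pairs of libraries with the same replicate number 7 correlated above 0.1 over all features, 3 of them in the torin 2 and combination groups of CH-157MN, and elsewhere the numbers gave no pairing for a block to use. Splits of 3 against 3 libraries number 10, so a share under 0.1 cannot occur. The real split alone, 1 of 10, gave as many calls in every such contrast over all features except torin 2 in IOMM-Lee (2 of 10) and the combination against digitoxin there (10 of 10, up to 2123 features), and strand-resolved except the latter (2 of 10, up to 233 genes). That split followed the own-strand share.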

Other observations

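The test of weaker removal of RNA without a tail was written before its result was seen, and all other tests in this part were chosen only after the result was seen.

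Features opposite the exons of coding genes held most counts outside the rRNA repeats in each library except CH-157MN torin 2 replicate 1, with 44.7%. Of the counts pooled over pairs, antisense features held 81.2% in the median library, and they were the higher in 65.1 to 76.8% of the pairs, so single pairs went both ways. Features with nothing annotated opposite held a median of 21.6%. Both shares follow from the pattern itself. A strand setting opposite to the kit and abundant antisense transcripts beside correctly counted coding genes therefore cannot be told apart here, and no biological explanation was tested.

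The 3 rRNA repeat features held about 4% of counts in CH-157MN DMSO replicate 1 and IOMM-Lee digitoxin replicate 3. Line or treatment does not account for it, since the lowest share among the other libraries of these 2 groups was 73.7%. Weaker removal of RNA without a poly(A) tail in the other 22 libraries may account for it: of these, 0 had a lower share of other RNAs without a tail than the higher of the 2 libraries. Over 2884 such features the shares were 0.0980 and 0.236% in the 2 libraries and 0.305 to 0.738% in the others, with a median of 0.472%. Whether the 2 libraries were prepared apart from the rest is not stated.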
